A study of Homo sapiens with 6 samples.

How the data were processed

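Expression was measured on Affymetrix arrays of 54675 probe sets, 1 array for each of 6 groups of human T cells. Per the labels' protocols, total RNA was isolated with a column kit, made into biotin-labelled cRNA and hybridized. A PCR step that amplified the cDNA is described for the retinoic acid sample, and for the other samples the labels only name the facility that did the labelling. The deposited values are intensity on a linear scale, from 0.10 to 72269. The software that summarized and scaled the probes is not given in the sources used here. The mean intensity of each array, leaving out 2% of probe sets at each end, was 500.07 in all 6, so the arrays were already on one scale and the values were taken as deposited. The median intensity, which such scaling leaves free, lay between 65.9 and 80.7.

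Groups were taken from the sample labels, and the comparisons, the floor, the fold threshold, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Values were set to at least the floor, the median intensity of their array, and turned into log2. Genes were named from the platform annotation, which listed 42898 probe sets, 41097 with 1 gene, 1801 with several and 0 with none, and 11777 probe sets were unnamed here. Entrez identifiers matched 41043 of the probe sets with 1 gene to current gene names, and 0 symbols changed. Of probe sets with 1 gene, 59 for sex-linked genes were left out. A gene was represented by its probe set of highest mean log2 intensity over the 6 arrays, which gave 19740 genes. It counted as measured in a comparison where at least 1 of the arrays was above its floor, and as higher or lower at a ratio of at least 2-fold. A ratio with 1 side at the floor is a bound and is written as at least so many fold. With 1 array per group no test was run.

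The genes named in each comparison were the 12 of largest and the 12 of smallest ratio past 2-fold, leaving out probe sets with several genes, symbols without a descriptive name, immunoglobulin and T cell receptor segments, and genes for which another probe set above the floor moved the other way by at least 0.5 log2. CCR10 was left out of this rule between the sorted arrays, but it stayed in the skin homing list. For the 2 comparisons that use both sorted arrays the smaller of both ratios decided. Members of the gene lists are named in addition. For the comparison of vitamin D with IL-12, added later, fewer genes are named. Each of 30 gene lists was described by the median log2 ratio of its measured members and by the percentile of that median among 10000 random lists of the same size, drawn within 10 bins of mean log2 intensity over the arrays. That percentile describes these arrays and is no test across samples. The lists cover homing receptors, nuclear receptor targets, T helper, regulatory, cytotoxic, activation and memory programmes, cell cycle, interferon, metabolic and stress programmes, markers of other blood cells, and control genes. 49 of 455 list genes had no probe set named here. The comparisons of both sorted arrays with IL-12 or vitamin D share the IL-12 or vitamin D array between the 2 ratios. Overlaps were counted only between comparisons without a common array, beside the number expected of independent lists.

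The code was tested on simulated data made from the unstimulated and retinoic acid arrays, with 200 genes changed on purpose. In the simulated comparison of vitamin D with unstimulated, on 13322 genes, 49.5% of changes of 2-fold, 89% of changes of 2.83-fold and 99.5% of changes of 5.66-fold were recovered, and 7.74% of unchanged genes passed 2-fold. In the simulated comparison of both sorted arrays with IL-12, on 14313 genes at the smallest change, these shares were 32%, 82.5%, 99% and 2.73%. The noise was taken from differences between both arrays, which also hold real effects that can raise it. Across 6650 genes, however, this pair had the smallest spread of log2 ratios of all pairs of arrays (0.38). The spread was 0.63 for unstimulated and vitamin D and 0.60 for IL-12 and CCR10-negative. Both arrays also have low control ratios, described in the Results, so the noise leaves out larger gaps in these ratios. For comparisons of wider spread the noise may therefore be too low. For the pair it was taken from, it was too high by the count of genes past 2-fold. Between these 2 arrays 5.43% of genes passed, real effects included, against 7.74% of unchanged genes in the simulation. A gene near 2-fold is thus uncertain, and the number of arrays limits the precision.

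The alternatives were quantile normalization, shifting each array to a common median, a floor at the 25th or the 75th percentile, a 3-fold threshold, the median over all probe sets of a gene, and leaving out probe sets of less specific design (suffix _s_at or _x_at). For comparisons of both sorted arrays, each array alone and the mean of both were used too. The direct comparison of vitamin D with IL-12, and the IL-12 array as reference for the lists, were chosen after the data were seen. Median scaling moved the median log2 ratio over all genes by 0.22 for retinoic acid against unstimulated, 0.18 for IL-12 against unstimulated, -0.28 for vitamin D against retinoic acid, 0.24 between the sorted arrays and -0.23 for vitamin D against IL-12. Quantile normalization moved it by -0.11 for vitamin D against retinoic acid, -0.10 for vitamin D against IL-12 and by less than 0.1 elsewhere. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.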

Results

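Gene expression was measured on 6 Affymetrix arrays, 1 array for each of 6 groups of human T cells. The labels give naive T cells of peripheral blood as the source and call the cells effector T cells. In 4 groups the cells were unstimulated, stimulated with retinoic acid (written Retinoid Acid in its label), with the Th1-inducing cytokine IL-12, or with calcitriol, the active hormone form of vitamin D3, called vitamin D here. In the remaining 2 groups the cells had received vitamin D plus IL-12 and were positive for CLA, a carbohydrate marker of skin-homing T cells, and either positive or negative for CCR10, a chemokine receptor of skin-homing T cells. The labels do not say whether the arrays share a donor. With 1 array per group there is no replicate check of any difference, so no p-value or standard deviation is given and ratios describe these arrays. The floor, each array's median intensity, lay between 65.9 and 80.7, and 11857 to 12117 of 19740 genes were above it. Of 26 genes not expected in T cells, such as albumin and insulin, 6 to 9 were above the floor on an array, 1 to 5 were above 2 times the floor and at most 1 was above 4 times the floor, so low intensities near the floor are of limited precision.

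The genes tied to the labels were read first. CCR10 had an intensity of 482 in the CCR10-positive array and 129.7 in the CCR10-negative array, 3.72-fold higher, 80.6 and 79.5 in the unstimulated and retinoic acid arrays (floors 77 and 65.9), and 47.5 and 57.5 in the IL-12 and vitamin D arrays (floors 68.1 and 79.8). In the vitamin D array itself CCR10 was therefore not above the floor. CYP24A1, the vitamin D 24-hydroxylase and a direct target of the vitamin D receptor, was above the floor in the vitamin D array (192) and the CCR10-positive array (420.2) and at the floor in the other 4. CCR9, the gut-homing receptor that retinoic acid induces in T cells, was above the floor in the retinoic acid array (955) and in no other. IFNG, the cytokine that IL-12 induces, had its highest intensity in the IL-12 array (4791) and its lowest in the vitamin D array (375).

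**Figure D1:**
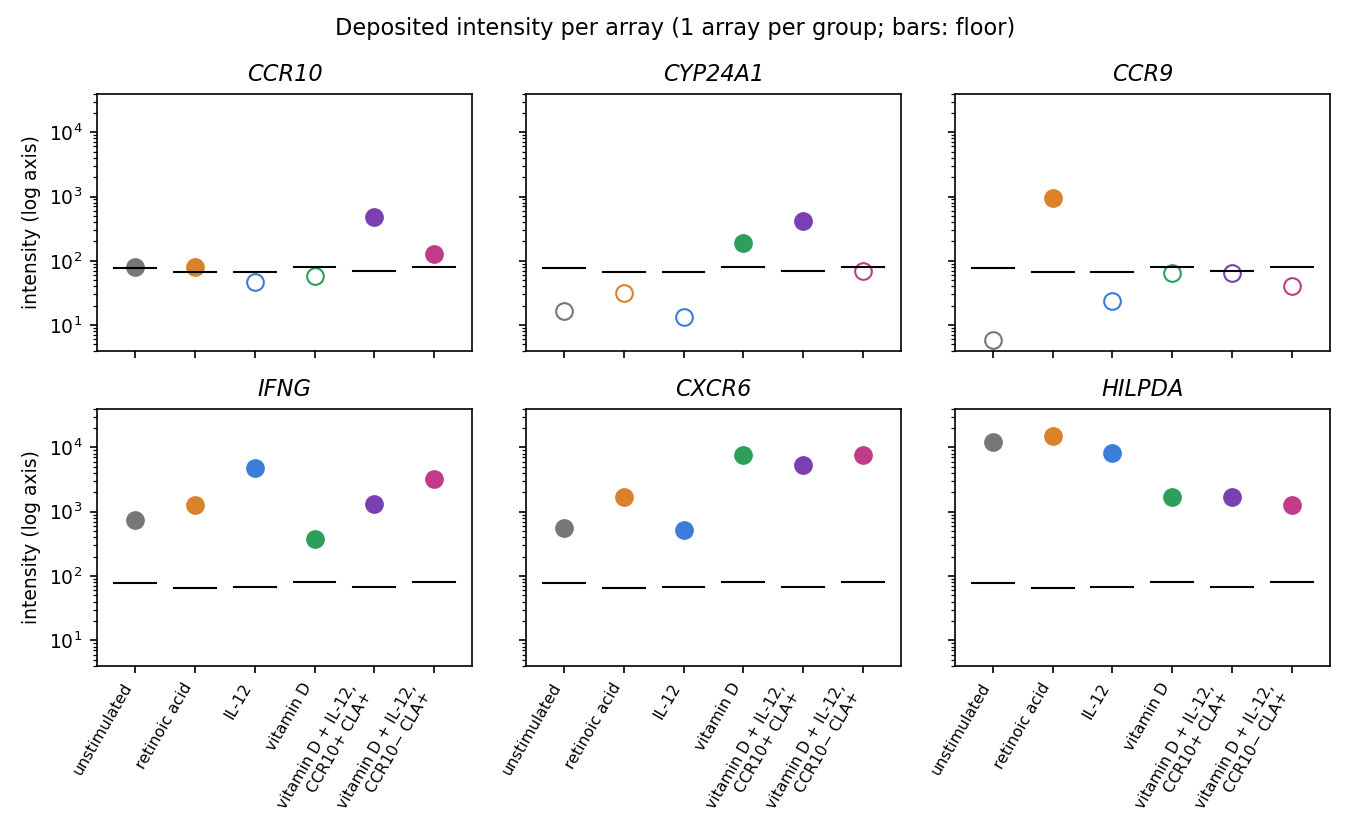
Deposited intensity (log axis) of 6 genes on the 6 arrays, 1 array per group on the horizontal axis; filled points lie above the array's floor, open points at or below it, and black bars mark the floor. CCR9 was above the floor in the retinoic acid array alone (955), and CXCR6 was higher and HILPDA lower in the 3 vitamin D arrays than in the other 3.

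The arrays also differed in the control probe sets that read the 3′ and the 5′ end of one transcript. The GAPDH ratio of 3′ over 5′ intensity was 1.59 in the retinoic acid and 2.11 in the unstimulated array, against 3.08 in the IL-12, 10.5 in the vitamin D, 3.99 in the CCR10-positive and 6.05 in the CCR10-negative array. The ACTB ratio was 5.95 and 9.3 in the retinoic acid and unstimulated arrays and 34.9 to 82.9 in the other 4. In both controls each array with vitamin D was above each array without it, so every comparison of vitamin D with its absence also sets a higher against a lower 3′ signal.

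**Figure D2:**
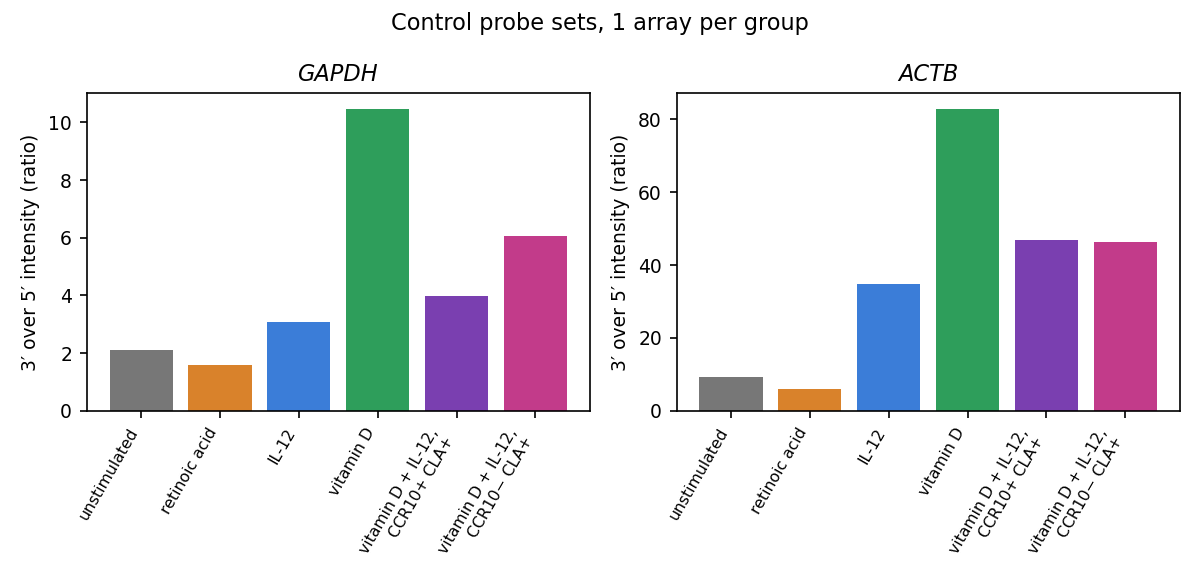
Ratio of 3′ over 5′ intensity of the GAPDH and ACTB control probe sets (vertical axes, from 0), 1 bar per array. The retinoic acid and unstimulated arrays have GAPDH ratios of 1.59 and 2.11, below the other 4 arrays.

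Vitamin D against no stimulus. In the vitamin D array 1025 of 13174 genes were at least 2-fold higher than in the unstimulated array and 657 at least 2-fold lower. The highest ratios were those of RASD1, a Ras-related GTPase first found as dexamethasone-induced (32.2-fold higher), the mitochondrial protein COXFA4L3 (23.5-fold), the growth factor BMP8B (at least 20.5-fold) and CXCR6, the receptor for CXCL16 (14.1-fold). They were followed by the poly(A) polymerase TENT5A (10.4-fold), the kinase PLK2 (10.02-fold), the tetraspanin TSPAN2 (9.98-fold), the pseudogene PMS2P5 (9.25-fold), the tubulin TUBB2A (8.4-fold), the GTPase RHOB (7.56-fold), RGS2, which limits G protein signalling (7.08-fold), and the secreted protein ISM1 (6.72-fold). The lowest ratios were led by HILPDA, a hypoxia-inducible lipid droplet protein (7.32-fold lower), the elongation factor ELOF1 (5.79-fold), GCSAM (5.66-fold), RABGGTB, a subunit of the enzyme that prenylates Rab proteins (5.42-fold), the ubiquitin ligase NEDD4L (at least 5.32-fold) and the small Cajal body RNA SCARNA17 (5.27-fold). PHF5A, a splicing factor (5.27-fold), APOL3 (5.25-fold), CDC42BPA (5.23-fold), NRROS (at least 5.08-fold), ANKZF1 (5.07-fold) and EGLN1, the oxygen-sensing prolyl hydroxylase (4.99-fold), completed this set. NEDD4L turned slightly higher without probe sets of less specific design.

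Of the 30 gene lists, 5 had a median log2 ratio outside the central 95% of 10000 random lists matched on mean expression, where 1.5 would be expected of lists drawn at random. The fixed lists share some members, and genes of one programme can vary together between any 2 arrays. More of them can therefore fall outside without an effect of treatment. Glycolysis had the lowest median (-0.70, below all 10000 random lists), with 6 of 18 members at least 2-fold lower and 0 higher. They included hexokinase HK2 (4.8-fold lower), the phosphofructokinase PFKP (2.41-fold), the bifunctional enzymes PFKFB3 (2.74-fold) and PFKFB4 (2.87-fold) and the aldolase ALDOC (2.91-fold). Retinoic acid receptor targets were also low (-0.38, percentile 0.42), led by the retinal reductase DHRS3 (3.31-fold lower) (the list median was positive with IL-12 as the reference), while CD38 was 3.31-fold higher. Interferon-stimulated genes (0.42, percentile 99.5), B cell and plasma cell markers (0.82, percentile 99.3) and dendritic cell markers (0.50, percentile 97.7) were high. Their members at least 2-fold higher included IFIT1 (4.18-fold), IFIT3 (3.83-fold), MS4A1, the B cell antigen CD20 (at least 5.87-fold), and CD80, a costimulatory ligand (2.92-fold). The list of vitamin D receptor targets lay inside the central range (0.26, percentile 93.6), with 6 of 25 measured members at least 2-fold higher, among them G0S2 (4.6-fold), STS (4.25-fold), CD93 (3.8-fold) and CYP24A1 (at least 2.5-fold). HILPDA, also a member of this list, was 7.32-fold lower. Lists of cell cycle genes (0.11), Th1 genes (0.33), regulatory T cell genes (0.18), skin homing receptors (0.20) and p53 response genes (-0.26) had medians inside it. CD8A was 2.31-fold higher and CD4 3.25-fold lower in the vitamin D array. The 2 arrays differ in 3′ over 5′ signal, and of 847 of these genes with another probe set above the floor, 70.6% had it moving the same way by any amount and 42% by at least 1.5-fold.

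Retinoic acid against no stimulus. The labels describe a PCR step that amplified the cDNA for the retinoic acid sample and do not say whether the unstimulated sample had it. Such a difference could not be told apart from retinoic acid. Both arrays have low control ratios, and 298 of 13141 genes were at least 2-fold higher and 415 at least 2-fold lower in the retinoic acid array. Together these were 5.43% of genes, below the 7.74% of unchanged genes that passed 2-fold between single arrays in the simulation. The simulation took its noise from these same 2 arrays, real effects included. The lower share therefore cannot tell whether the differences are noise. The highest ratios were those of COXFA4L3 (14.4-fold higher), the aspartic protease NAPSA (at least 13.5-fold), LZTFL1 (12.8-fold), CCR9 (at least 12.4-fold) and the chemokine receptor CCR1 (6.38-fold). The anion exchanger SLC26A4 (at least 5.04-fold), the mitochondrial arginase ARG2 (5.03-fold), PIGS (4.68-fold), ITPRIPL2 (4.25-fold), APOL4 (at least 4.24-fold), the granule protein NKG7 (4.0-fold) and ASB2, a ubiquitin ligase adaptor known to be induced by retinoic acid in leukaemia cells (3.72-fold), followed. Among the lowest were ADTRP (9.18-fold lower), the SLAM family receptor LY9 (6.32-fold), the integrin subunit ITGA6 (6.07-fold), the homeobox gene MEOX1 (at least 5.09-fold), ANKFN1 (at least 5.07-fold), the ephrin receptor EPHA4 (at least 4.8-fold) and FGFBP2 (4.46-fold). SBK1 (4.35-fold), RIN1 (at least 4.22-fold), ZNF585B (at least 4.21-fold), TOM1L2 (4.09-fold) and ECRG4 (at least 4.09-fold) were also in this set.

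Cytotoxic granule genes had the highest list median in this comparison (0.97, above all 10000 random lists), with 6 of 12 members at least 2-fold higher, including GZMA (3.51-fold), GZMB (2.65-fold) and granulysin, GNLY (2.24-fold). Interferon-stimulated genes (0.53, above all 10000 random lists) were also high, with OASL (2.85-fold higher), IFIT3 (2.66-fold), IFIT1 (2.36-fold) and IFI6 (2.35-fold). Gut homing receptors (0.36, percentile 99.6) and retinoic acid receptor targets (0.24, percentile 98.3) were high as well, and both lists hold CCR9 and ITGB7. CXCR6 was 3.06-fold higher, the integrin subunit ITGB7 had a ratio of 1.8-fold and DHRS3 one of 1.77-fold, both under the threshold. Metallothioneins (0.57, percentile 99.92), amino acid and ER stress genes (0.29, percentile 99.92), glycolysis (0.23, percentile 99.8), pan-T cell markers (0.23, percentile 98.6) and the 5 measured red cell and platelet markers (0.41, percentile 98.9) also had medians above the central range, while the 5 measured dendritic cell markers (-0.53, percentile 1.51) lay below it. The share of higher genes among these was 41.8% as deposited, 58.3% after quantile normalization and 76.8% after median scaling. The red cell and platelet median turned negative without probe sets of less specific design.

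IL-12 against no stimulus. In the IL-12 array 634 of 13182 genes were at least 2-fold higher and 565 at least 2-fold lower. The highest ratios included the granule protease GZMK (7.04-fold higher), IFNG (6.51-fold), KBTBD11 (8.19-fold), P-cadherin, CDH3 (7.2-fold), DDIT4L (7.18-fold), the cysteine dioxygenase CDO1 (6.23-fold), ITGA6 (5.92-fold) and the cytokine receptor subunit IL23R (5.29-fold). USP31 (5.45-fold), SLC26A11 (5.32-fold), the pseudogene ZNF37BP (4.99-fold) and the heterochromatin protein CBX5 (4.9-fold) were in the same set. The lowest were LY9 (12.4-fold lower), RASEF (6.78-fold), the noncoding RNA GLIDR (6.1-fold), SLC35F3 (5.99-fold), the heat shock gene HSPA6 (5.41-fold), CHI3L2 (5.33-fold), FAM171A1 (4.69-fold) and the complement receptor C3AR1 (4.58-fold). ANKFN1 (4.8-fold), KLHL29 (4.79-fold), KAZN (at least 4.58-fold) and a probe set assigned to MIR302B (5.57-fold) also belonged to it.

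Cytotoxic granule genes (0.80, above all 10000 random lists) and the Th1 and IL-12 response list (0.30, percentile 98.5) had medians above the central range. In the Th1 list 4 of 21 members were at least 2-fold higher, among them IL18RAP, a subunit of the IL-18 receptor (2.46-fold), and EOMES (2.64-fold), and 3 were at least 2-fold lower, including STAT4, which signals for IL-12 (2.03-fold), and CXCR3 (3.65-fold). Interferon-stimulated genes had the lowest median of these (-0.53, percentile 0.020), with OASL 2.58-fold lower. Naive and memory T cell genes (-0.48, percentile 0.16), retinoic acid receptor targets (-0.38, percentile 1.52), pan-T cell markers (-0.37, percentile 0.83), glycolysis (-0.36, percentile 0.17), housekeeping genes (-0.31, percentile 0.85) and ribosomal protein genes (-0.30, percentile 2.47) were also below the range. The ribosomal protein median turned positive after quantile normalization, the housekeeping median turned positive without probe sets of less specific design, and the Th1 median turned negative when all probe sets of a gene were used. The share of higher genes among these was 52.9% as deposited, 61.6% after quantile normalization and 75.5% after median scaling. The 2 arrays differ in 3′ over 5′ signal.

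Vitamin D against retinoic acid. This direct comparison of both vitamin-derived hormones gave 1336 genes at least 2-fold higher and 895 at least 2-fold lower in the vitamin D array, of 13206. BMP8B (17.2-fold higher), RASD1 (16.4-fold), PLK2 (13.8-fold), PMS2P5 (13-fold), TUBB2A (at least 12.3-fold) and ADTRP (11.3-fold) had the highest ratios. They were followed by ZNF652 (9.38-fold), the endocytic receptor LY75 (8.58-fold), EPS8 (8.26-fold), TENT5A (7.66-fold), ZNF37BP (7.46-fold) and KLF2, a transcription factor of T cell recirculation (7.69-fold). On the other side stood CCR9 (at least 12-fold lower), ELOF1 (10.7-fold), GPR146 (9.47-fold), NAPSA (9.22-fold), HILPDA (9.15-fold) and LZTFL1 (8.44-fold), with the collagen chaperone SERPINH1 (at least 8.01-fold), the phosphatase PTPN3 (at least 7.95-fold), COA1 (7.33-fold), SCARNA17 (7.19-fold), EPB41L4B (at least 7.02-fold) and PHF5A (6.91-fold). COA1 turned higher without probe sets of less specific design. Glycolysis (-0.93, below all 10000 random lists), cytotoxic granule genes (-0.50, percentile 0.98), amino acid and ER stress genes (-0.44, percentile 0.75), pan-T cell markers (-0.45, percentile 2.13) and retinoic acid receptor targets (-0.32, percentile 0.74) were lower in the vitamin D array than in the retinoic acid array. The 3 CD8 markers (1.02, percentile 98.8), dendritic cell markers (0.90, percentile 99.9) and B cell markers (0.92, percentile 97.7) were higher. The share of higher genes among these was 59.9% as deposited, 48.8% after quantile normalization and 29% after median scaling. The comparison sets the highest against the lowest 3′ over 5′ control ratio. A PCR step that amplified the cDNA is described for the retinoic acid sample alone.

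Vitamin D plus IL-12 against IL-12 alone. Each array of vitamin D plus IL-12, CCR10-positive and CCR10-negative, was set against the IL-12 array, and a gene was counted where both ratios passed 2-fold in one direction. Of 13829 genes, 264 were at least 2-fold higher and 235 at least 2-fold lower in both. In this paragraph the ratio of the CCR10-positive array is given first. The highest were HSPA6 (20.01-fold and 26.5-fold higher), G0S2, an inhibitor of triglyceride lipase (15.7-fold and 13.2-fold), COXFA4L3 (22.6-fold and 13.2-fold), TSPAN2 (14.4-fold and 12.6-fold), RASD1 (11.6-fold and 15.7-fold) and CXCR6 (9.99-fold and 14.3-fold). TENT5A (8.45-fold and 10.1-fold), the Rab GTPase RAB31 (at least 7.18-fold and at least 10.4-fold), the ketone body enzyme OXCT2 (at least 7.14-fold and at least 7.66-fold), the pseudogene RRN3P2 (6.54-fold and 6.96-fold), RGS2 (5.88-fold and 6.52-fold) and the laminin chain LAMB3 (at least 7.25-fold and at least 5.79-fold) followed. The lowest were SHISA2 (8.11-fold and 10.1-fold lower), EPB41L4B (7.47-fold and 10.01-fold), GPR146 (7.34-fold and at least 7.09-fold), PTPN3 (7.72-fold and at least 6.88-fold), IL23R (at least 6.88-fold and 5.5-fold) and FAM13A (5.36-fold and 5.88-fold). The hyaluronan receptor LAYN (5.21-fold and 8.03-fold), HILPDA (4.83-fold and 6.52-fold), DNAJC12 (4.59-fold and 9.98-fold), the G protein subunit GNA15 (4.45-fold and 6.49-fold), the magnesium transporter SLC41A2 (4.17-fold and 9.29-fold) and the transcription factor SP5 (at least 4.88-fold and at least 4.15-fold) completed the set. Without probe sets of less specific design FAM13A was near equal in the arrays.

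In both arrays vitamin D receptor targets were above the central range of random lists against IL-12 (0.57, above all 10000 random lists in the CCR10-positive and 0.44, percentile 99.4 in the CCR10-negative array), with ALOX5, the 5-lipoxygenase, 2.33-fold and 4.77-fold higher and STS, steroid sulfatase, 7.61-fold and 4.09-fold higher. HILPDA, also a member of this list, was 4.83-fold and 6.52-fold lower. CYP24A1 was at least 6.17-fold higher in the CCR10-positive array and at the floor in the CCR10-negative and IL-12 arrays. Interferon-stimulated genes were high in both (0.58, above all 10000 random lists in the CCR10-positive and 0.82, above all 10000 random lists in the CCR10-negative array), and so were B cell markers (0.86, percentile 99.9 in the CCR10-positive and 0.75, percentile 98.4 in the CCR10-negative array). Glycolysis was low in both (-0.35, percentile 0.030 in the CCR10-positive and -0.52, percentile 0.060 in the CCR10-negative array). Th1 genes (0.55, percentile 99.9), cytotoxic granule genes (0.57, percentile 99.7), chemokine receptors and trafficking genes outside the homing lists (0.76, percentile 99.8), immediate early and heat shock genes (0.36, percentile 97.7) and dendritic cell markers (0.58, percentile 97.8) were above the range in the CCR10-negative array. In the CCR10-positive array skin homing genes (0.45, percentile 98.4), gut homing genes (0.44, percentile 99.5) and Th2 genes (0.70, percentile 99.98) were above it and Th17 and Th22 genes (-0.36, percentile 2.19) below it. The skin homing list holds CCR10, for which these cells were sorted, and genes of CLA synthesis, so the sort itself can raise its median. Both ratios share the IL-12 array, and these cells differ from those of the IL-12 array in CLA or CCR10 sorting and in 3′ over 5′ signal as well as in vitamin D. The share of higher genes among these was 52.9% as deposited, 43.7% after quantile normalization and 37.1% after median scaling.

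The vitamin D array was also set directly against the IL-12 array, a comparison added after the control ratios were seen. Both control ratios were higher in the vitamin D array. It gave 942 genes at least 2-fold higher and 620 at least 2-fold lower in the vitamin D array, of 13215. COXFA4L3 (42.1-fold higher), ISM1 (at least 25.1-fold), HSPA6 (24.2-fold), BMP8B (18.1-fold), RASD1 (17.5-fold), the chemokine receptor CCR2 (16.4-fold) and CXCR6 (14.7-fold) led the higher genes, and SLC41A2 (13-fold lower), IFNG (12.8-fold), EPB41L4B (at least 11.1-fold), SHISA2 (10.9-fold), the kinase MAP3K8 (9.51-fold) and GZMK (8.6-fold) the lower ones. Without probe sets of less specific design EPB41L4B turned slightly higher. Interferon-stimulated genes (0.99, above all 10000 random lists), B cell markers (1.14, percentile 99.9), the 3 CD8 markers (1.05, percentile 99.6) and dendritic cell markers (0.74, percentile 99.7) were higher, and so were ribosomal protein genes (0.29, percentile 98.2), whose median turned negative after quantile normalization. Glycolysis (-0.41, percentile 0.31), cholesterol synthesis (-0.47, percentile 0.80), amino acid and ER stress genes (-0.31, percentile 2.15) and Th1 genes (-0.29, percentile 1.17) were lower, the last with a median that turned positive when all probe sets of a gene were used. CD8A was 2.29-fold higher in the vitamin D array. The share of higher genes among these was 60.3% as deposited, 45.8% after quantile normalization and 30.2% after median scaling.

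Vitamin D plus IL-12 against vitamin D alone. Both arrays of vitamin D plus IL-12 shared 118 genes at least 2-fold higher and 124 at least 2-fold lower than in the vitamin D array, of 13804. Together these were 1.75% of genes, below the 2.73% of unchanged genes that passed in the simulation of both sorted arrays against IL-12. That simulation took its noise from the unstimulated and retinoic acid arrays, so the lower share cannot tell whether these differences are noise. With the CCR10-positive array given first again, the highest were ITGA6 (8.08-fold and 7.1-fold higher), GZMK (6.16-fold and 9.3-fold), STEAP1 (5.35-fold and 6.22-fold), the transcription factor MAF (5.17-fold and 4.69-fold), CRISPLD1 (4.57-fold and 5.57-fold) and TRERF1 (4.61-fold and 4.49-fold). MAP3K8 (4.39-fold and 5.17-fold), CDO1 (4.7-fold and 4.1-fold), ZNF319 (at least 5.2-fold and at least 4.06-fold), paxillin, PXN (4.17-fold and 3.75-fold), the ATP-gated channel P2RX5 (3.58-fold and 4.04-fold) and IFNG (3.52-fold and 8.52-fold) followed. The lowest were ISM1 (4.75-fold and 7.2-fold lower), the histone deacetylase HDAC5 (at least 5.36-fold and at least 4.55-fold), NELL2 (4.11-fold and 6.96-fold), MAN1C1 (3.83-fold and 7.42-fold), SESN3 (3.78-fold and 7.73-fold), the integrin subunit ITGA2 (3.73-fold and 3.93-fold) and SLC35F3 (3.43-fold and 7.36-fold). FAM13A (3.11-fold and 3.41-fold), IL6 (at least 3.66-fold and at least 3.11-fold), GATAD1 (3.06-fold and 3.33-fold), DUSP3 (3.05-fold and 3.15-fold) and JAML (3.0-fold and 2.91-fold) were also in this set. Th1 genes were above the central range in both arrays (0.24, percentile 99 in the CCR10-positive and 0.70, above all 10000 random lists in the CCR10-negative array), with IL18RAP 2.23-fold and 3.46-fold higher and SOCS3, a feedback inhibitor of cytokine signalling, 4.08-fold and 5.43-fold higher. Naive and memory T cell genes (-0.48, below all 10000 random lists in the CCR10-positive and -0.38, percentile 0.33 in the CCR10-negative array) and the 3 CD8 markers (-0.88, percentile 0.045 in the CCR10-positive and -1.08, percentile 0.035 in the CCR10-negative array) were below it in both. Amino acid and ER stress genes were above it in both (0.28, percentile 99.7 in the CCR10-positive and 0.26, percentile 99.3 in the CCR10-negative array). In the CCR10-positive array vitamin D receptor targets (0.14, percentile 98.8) and metallothioneins (0.38, percentile 98.3) were above it too, as were T cell activation genes (0.35, percentile 99.8), whose median turned negative when all probe sets of a gene were used. Interferon-stimulated genes (-0.42, below all 10000 random lists), dendritic cell markers (-0.55, percentile 0.75) and ribosomal protein genes (-0.23, percentile 0.42) were below it there, the last with a median that turned positive after quantile normalization. In the CCR10-negative array natural killer cell markers (0.84, percentile 99.94), B cell markers (0.52, percentile 99), cytotoxic granule genes (0.47, percentile 99.98), cholesterol synthesis (0.35, percentile 99.5) and the other chemokine receptors and trafficking genes (0.47, percentile 99.5) were above it, the last with a median that turned negative without probe sets of less specific design. Glycolysis (-0.24, percentile 1.16) and cell cycle genes (-0.17, percentile 2.5) were below it there. Both ratios share the vitamin D array, and the arrays differ in CLA or CCR10 sorting and in 3′ over 5′ signal, lower than in the vitamin D array, as well as in IL-12. The share of higher genes among these was 48.8% as deposited, 57.8% after quantile normalization and 63.8% after median scaling.

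CCR10-positive against CCR10-negative cells. Among CLA-positive cells given vitamin D plus IL-12, 233 of 13157 genes were at least 2-fold higher and 458 at least 2-fold lower in the CCR10-positive array. Together these were 5.25% of genes, below the 7.74% of unchanged genes that passed 2-fold between single arrays in the simulation. The noise of the simulation came from the unstimulated and retinoic acid arrays, so its rate need not hold here. The lower share cannot tell whether the differences between the sorted arrays are noise. Apart from CCR10, the highest were the carbonic anhydrase CA2 (5.6-fold higher), CYP24A1 (at least 5.21-fold), the desmosomal cadherin DSG2 (at least 4.15-fold), GAS2L3 (3.94-fold), ARHGAP5 (3.93-fold), the immunoglobulin joining chain JCHAIN (3.77-fold), RPL10L (3.74-fold) and GATM, an enzyme of creatine synthesis (3.71-fold). The calcium-binding protein GCA (3.68-fold), TNFRSF8, the activation antigen CD30 (3.67-fold), the proton pump subunit ATP12A (3.65-fold) and PIP4P2 (3.62-fold) followed, and ATP12A turned slightly lower with a floor at the 75th percentile. Higher in the CCR10-negative array were MYL10 (at least 8.52-fold lower in CCR10-positive cells), the chemokine CCL4 (7.88-fold), the aldo-keto reductase AKR1C3 (7.29-fold), the natural killer adaptor SH2D1B (at least 5.98-fold), NPDC1 (at least 5.5-fold), FUT7, the fucosyltransferase that makes CLA (at least 4.95-fold), and KLRB1, the receptor CD161 (4.55-fold). CAPN10 (at least 4.4-fold), CCDC163 (4.29-fold), FBXL15 (4.16-fold), the G protein subunit GNAO1 (4.11-fold) and GABARAPL1 (4.04-fold) were also in this set.

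Cytotoxic granule genes had the lowest list median in the CCR10-positive array (-0.79, below all 10000 random lists), with 5 of 12 members at least 2-fold lower and 0 higher, among them GNLY (3.11-fold lower), NKG7 (2.33-fold), KLRD1 (2.26-fold) and GZMA (2.13-fold). Th1 genes (-0.49, below all 10000 random lists) included EOMES (2.37-fold lower) and IFNG (2.42-fold), and natural killer cell markers (-0.70, percentile 1.89) and the other chemokine receptors and trafficking genes (-0.46, percentile 0.31) were low too, with CCR1 2.97-fold lower. Interferon-stimulated genes (-0.26, percentile 0.37) and ribosomal protein genes (-0.26, percentile 0.55) also lay below the central range, the latter with a median that turned positive after quantile normalization. Vitamin D receptor targets were the list above it (0.23, percentile 99.2), with CYP24A1 at least 2-fold higher and ALOX5 2.05-fold lower. Lists of skin homing genes (-0.20), gut homing genes (0.09), Th2 genes (-0.10), Th17 and Th22 genes (-0.38), regulatory T cell genes (-0.05), glycolysis (0.17) and cell cycle genes (0.05) had medians inside it. B cell markers also lay inside it (-0.48), while MS4A1 was 3.82-fold lower and JCHAIN 3.77-fold higher. Monocyte and macrophage markers had a median of -0.35 over the 6 measured. The share of higher genes among these was 33.7% as deposited, 52.4% after quantile normalization and 74.1% after median scaling. Of 283 of the counted genes with another probe set above the floor, 68.2% had it moving the same way by any amount and 27.6% by at least 1.5-fold. The GAPDH ratio of 3′ over 5′ intensity was 3.99 in the CCR10-positive and 6.05 in the CCR10-negative array. The ACTB ratios of these arrays were near equal (47 and 46.4).

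**Figure D3:**
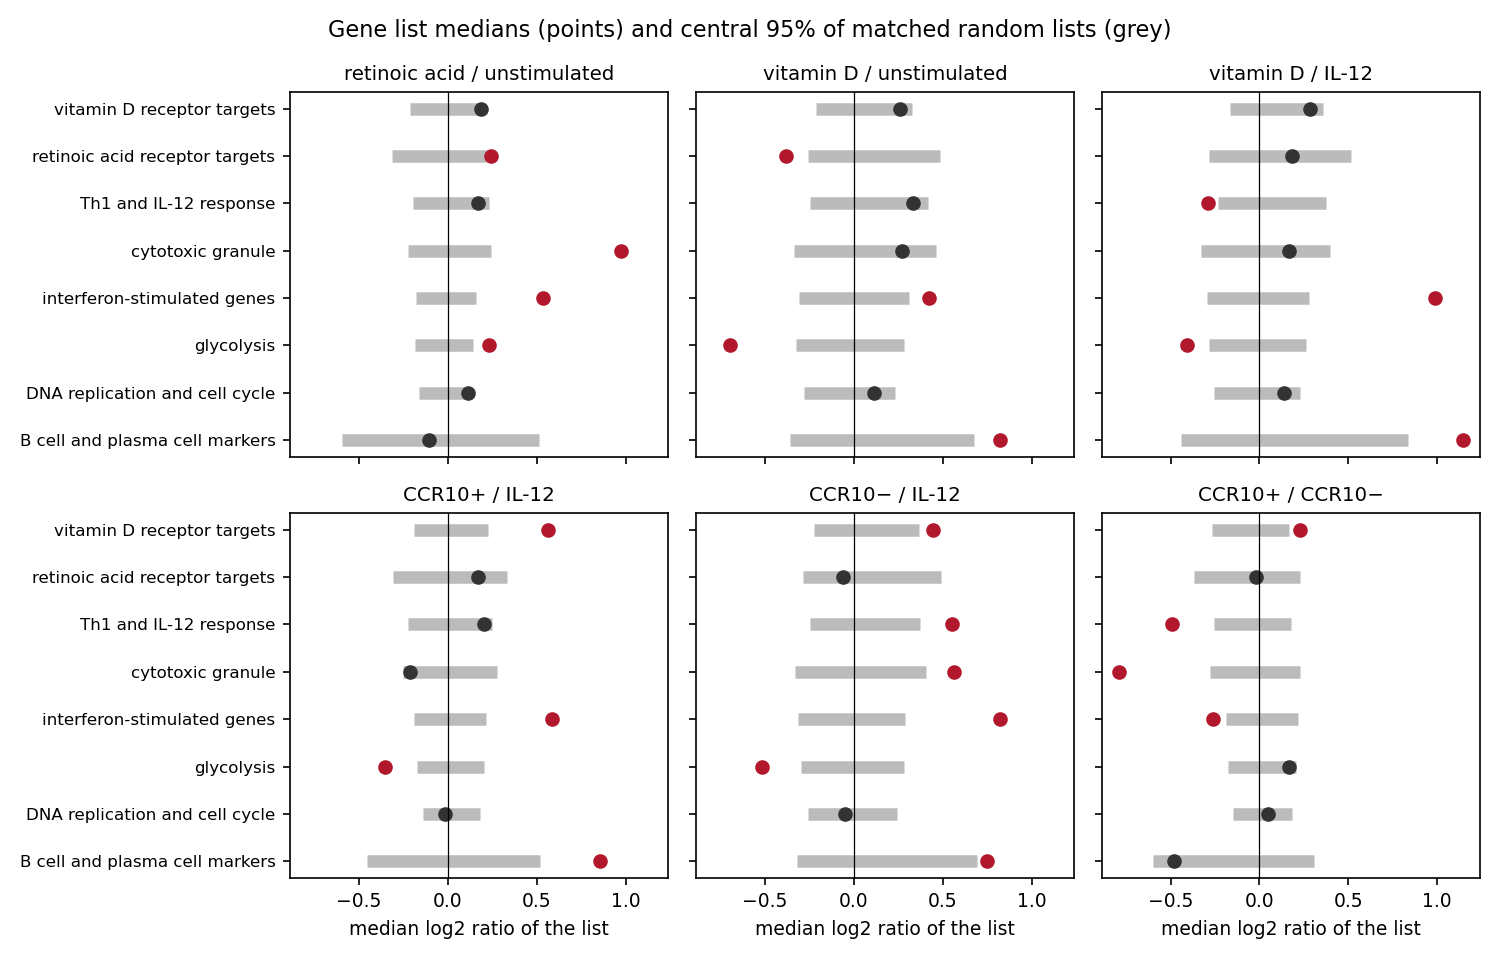
Median log2 ratio (horizontal axis) of 8 gene lists (vertical axis) in 6 comparisons of single arrays; points are list medians, red where they lie outside the grey bar, which spans the central 95% of 10000 random lists matched on mean expression. Glycolysis lies to the left in all 4 comparisons of a vitamin D array with an array without it, and cytotoxic granule genes lie at 0.97 for retinoic acid against unstimulated and at -0.79 for CCR10-positive against CCR10-negative.

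Genes shared by comparisons without a common array. Vitamin D was present in the numerator of both vitamin D against unstimulated and vitamin D plus IL-12 against IL-12, which share no array, and both control ratios were higher in the numerator of each. Of 12293 genes measured in both, 115 were at least 2-fold higher in both, where 21.4 would be expected of independent lists and 26.8 of lists independent within 10 bins of intensity. For lower genes the numbers were 99, 12.1 and 13. Opposite directions were seen for 6 and 4 genes. The shared higher genes were led by COXFA4L3, RASD1, CXCR6, TSPAN2, TENT5A and OXCT2, and included the zinc exporter SLC30A1 (2.77-fold higher against unstimulated), the phosphatase DUSP1 (3.2-fold), EOMES (5.12-fold) and the B cell genes MS4A1 (at least 5.87-fold) and BANK1 (at least 2.81-fold). The shared lower genes were led by HILPDA, FAM13A (near equal in the sorted and IL-12 arrays without probe sets of less specific design), GPR146, SLC41A2 and DNAJC12, and included HK2 (4.8-fold lower against unstimulated), PFKFB4 (2.87-fold), DHRS3 (3.31-fold), the lipoprotein receptor VLDLR (3.45-fold) and the costimulatory receptor ICOS (2.37-fold). Across 6650 genes above the 75th percentile on all arrays, the log2 ratio of vitamin D over unstimulated correlated with that of the CCR10-positive array over IL-12 with a Pearson r of 0.55 and a Spearman rho of 0.511, and with that of the CCR10-negative array over IL-12 with 0.502 and 0.458. These are correlations across genes, which are not independent replicates.

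**Figure D4:**
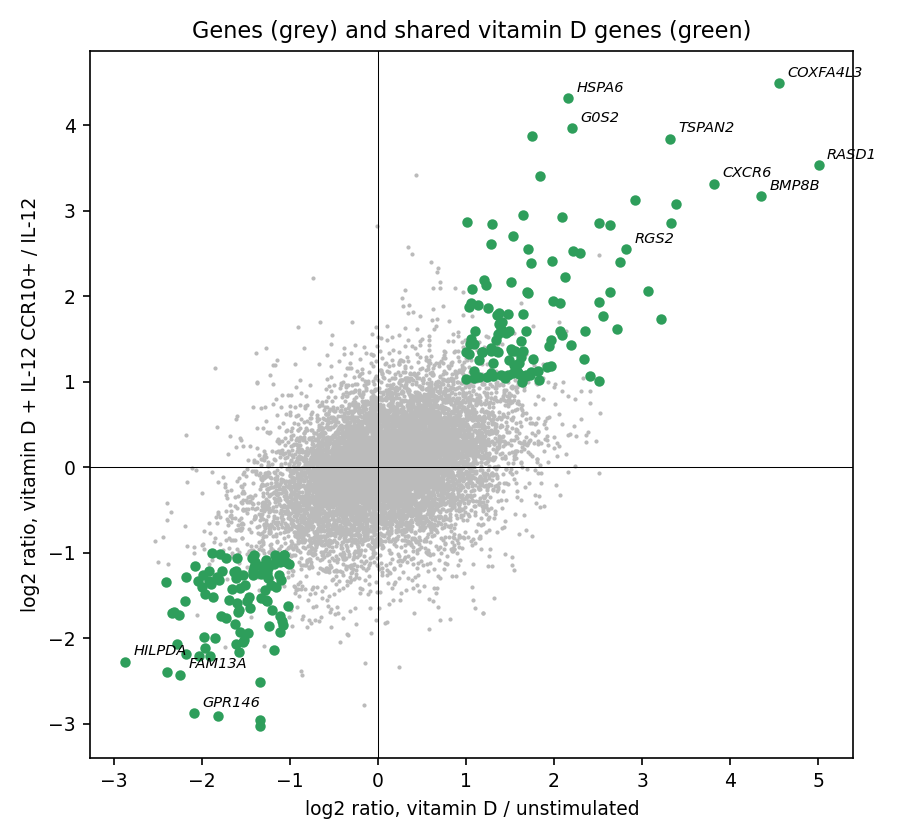
Log2 ratio of vitamin D over unstimulated (horizontal axis) against that of CCR10-positive over IL-12 (vertical axis), 1 point per gene. Green points are the 115 higher and 99 lower shared vitamin D genes, which passed 2-fold in these ratios and in that of CCR10-negative over IL-12.

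IL-12 was likewise common to the numerators of IL-12 against unstimulated and vitamin D plus IL-12 against vitamin D. Of 12276 genes measured in both, 46 were at least 2-fold higher in both (5.68 expected of independent lists, 6.78 within intensity bins) and 30 at least 2-fold lower (4.92 and 6.41), with 3 and 4 in opposite directions. GZMK, ITGA6, MAP3K8, CRISPLD1, CDO1, IFNG, IL18RAP (2.46-fold higher against unstimulated) and IL1RL1, the receptor for IL-33 (3.05-fold), were among the higher genes. MAN1C1, SESN3, ISM1, SLC35F3, NELL2, CCR2 (3.92-fold lower against unstimulated), CCL5 (2.06-fold) and CRTAM (2.13-fold) were among the lower ones. The correlation across genes was 0.356 with the CCR10-positive array over vitamin D and 0.212 with the CCR10-negative array over vitamin D (Pearson r; Spearman rho 0.282 and 0.149). Pairs of ratios with no common array or treatment gave Pearson r values of 0.354 and 0.357 where both ratios set higher against lower control ratios (IL-12 over unstimulated with vitamin D over retinoic acid, and vitamin D over unstimulated with IL-12 over retinoic acid). They gave -0.02 and -0.15 for retinoic acid over unstimulated with vitamin D over IL-12 and with CCR10-positive over CCR10-negative. The control ratios are higher in IL-12 than in unstimulated and lower in the sorted arrays than in vitamin D.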

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

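Of the tests below, that of an added effect of the gap in control ratios, that of the gap as the whole cause and that of the gap for glycolytic genes were chosen after their results were seen, and those on hypoxia targets and on further B cell genes were set down before. The count of B cell genes near the floor, the other B cell transcripts named and the reading of both as leaving B cells open were added after the results were seen. A signal outside the comparisons was the ratio of 3′ over 5′ intensity of the control probe sets, which was above that of the unstimulated array in 4 arrays. The GAPDH ratio was 2.11 in the unstimulated array and 3.08 in the IL-12, 10.5 in the vitamin D, 3.99 in the CCR10-positive and 6.05 in the CCR10-negative array. The ACTB ratio was 9.3 in the unstimulated array and 34.9, 82.9, 47 and 46.4 in the same 4.

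The first pattern is that the vitamin D and IL-12 arrays differ from the unstimulated array in more genes (1682 and 1199) than the retinoic acid array does (713). An added effect that goes with the gap in control ratios, called preparation here, is compatible with the data. Vitamin D over unstimulated and IL-12 over retinoic acid share no array or treatment, but both set higher against lower control ratios. They correlated across 6650 genes with r = 0.357. The labels name no batch of preparation, and what gave the gap was not tested. Preparation and vitamin D as the whole cause for the vitamin D array cannot be told apart: the shared vitamin D genes, higher and lower together, are 5.38 times as many as independent lists within intensity bins would give, but the control ratios of both sorted arrays are also above those of the IL-12 array, so preparation could give such an overlap too. Donor and culture, which have no label, stay open as well.

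The second pattern is the lower signal of glycolytic genes in the 3 vitamin D arrays, and preparation as its cause cannot be told apart from vitamin D: against the IL-12 array the list lay at or under percentile 0.31 of random lists in all 3, but their control ratios were also above those of that array. The list followed the control ratios without vitamin D, at 0.23 (percentile 99.8) in retinoic acid and -0.36 (percentile 0.17) in IL-12 over unstimulated, but not in CCR10-negative over vitamin D, where the control ratios were lower and so were glycolysis (-0.24, percentile 1.16) and the hypoxia list named next (-0.30, percentile 0.25). That list also differed between both sorted arrays, at 0.35 (percentile 99.91) in CCR10-positive, of lower GAPDH ratio, over CCR10-negative. The ACTB ratio was near equal in these 2 arrays (47 and 46.4). A candidate explanation in biology is a lower hypoxia response with vitamin D, since a second list of targets of hypoxia-inducible factor had medians of -0.51 (22 measured) against unstimulated, -0.79 (21) in CCR10-positive over IL-12 and -0.73 (21) in CCR10-negative over IL-12, the first at percentile 0.030 and the others below all 10000 random lists; in IL-12 over unstimulated this second list was inside the central range (0.05, percentile 72.5), while in retinoic acid over unstimulated it was above it (0.17, percentile 98.9), as glycolysis was. It stays a hypothesis, since preparation, cell density, medium or harvest could give the same and each group is 1 array.

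The third pattern is the higher signal of the B cell genes MS4A1, BANK1 and BLNK in the 3 vitamin D arrays, highest in the CCR10-negative array, where MS4A1 was 13-fold and BANK1 9.46-fold higher than in the IL-12 array. A second list of B cell genes, 14 of them measured, had a median of 0.30 there (percentile 76.1), but 7 of these were under 2 times the floor in the CCR10-negative array, and activated T cells also express at least 3 (CD37, POU2AF1 and CIITA), so this median does not exclude B cells as the limit set for it beforehand would have. Among other B cell transcripts IGHM was 9.23-fold, PAX5 4.58-fold, FCRLA at least 2.93-fold and IGLC1 2.2-fold higher. CD79A was 1.51-fold, CD79B 1.68-fold, IGKC at least 1.63-fold and CD37 1.84-fold higher, while HLA-DRA was 1.65-fold and CIITA at least 2.06-fold lower. Of the 14 list genes 10 were higher and 4 lower there. IGKC (282.9 against 110.9) and JCHAIN (431.9 against 114.6) were instead higher in the CCR10-positive than in the CCR10-negative array. Of 16 genes of the second list measured between the sorted arrays, 6 were higher and 10 lower in the CCR10-positive array. B cells among the T cells therefore cannot be told apart from expression of these genes in T cells. The study's design names sorted T cells, and their purity is not given in the sources used here.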

How the results depend on the processing

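The IL-12 array as reference for lists and the comparison of vitamin D with IL-12 were chosen after the data were seen. No paired analysis was possible because the labels carry no replicate numbers and each group is 1 array. Of 547 ratios of single genes past 2-fold, 547 kept their direction after quantile normalization and 518 stayed past 2-fold, and after median scaling the numbers were 547 and 486. Median scaling shifts all genes of an array alike, here by at most 0.28 log2, so it could not reverse a ratio past 2-fold. Quantile normalization moved the medians by at most 0.11, so reversals were unlikely there too. With the median over all probe sets 545 kept their direction and 433 stayed past 2-fold. Of 86 list medians outside the central range, 86 kept their sign after median scaling and 82 after quantile normalization. Signal over background limits dim genes: with a floor at the 75th percentile 466 of these ratios were measured, 464 kept their direction and 382 stayed past 2-fold. Counts moved more, and where no cause is given it was not tested.

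A floor at the 25th percentile, which admits dimmer probe sets, gave 2685 higher and 1818 lower for vitamin D against unstimulated, 1564 higher and 2333 lower for retinoic acid against unstimulated, 1924 higher and 2148 lower for IL-12 against unstimulated and 3350 higher and 1810 lower for vitamin D against retinoic acid. It gave 870 higher and 635 lower for both sorted arrays against IL-12, 516 higher and 760 lower for both sorted arrays against vitamin D, 1221 higher and 2169 lower for CCR10-positive against CCR10-negative and 2566 higher and 1500 lower for vitamin D against IL-12. It gave 274 higher and 169 lower for the shared vitamin D genes and 139 higher and 177 lower for the shared IL-12 genes. A floor at the 75th percentile, which leaves fewer genes, gave 483 higher and 398 lower for vitamin D against unstimulated, 94 higher and 66 lower for retinoic acid against unstimulated, 311 higher and 206 lower for IL-12 against unstimulated and 614 higher for vitamin D against retinoic acid. It gave 103 higher and 143 lower for both sorted arrays against IL-12, 54 higher and 33 lower for both sorted arrays against vitamin D, 96 higher and 72 lower for CCR10-positive against CCR10-negative and 356 higher and 374 lower for vitamin D against IL-12. It gave 52 higher for the shared vitamin D genes and 24 higher and 14 lower for the shared IL-12 genes. A 3-fold threshold, which is stricter by construction, gave 197 higher and 132 lower for vitamin D against unstimulated, 37 higher and 58 lower for retinoic acid against unstimulated, 135 higher and 87 lower for IL-12 against unstimulated and 295 higher and 241 lower for vitamin D against retinoic acid. It gave 61 higher and 44 lower for both sorted arrays against IL-12, 25 higher and 13 lower for both sorted arrays against vitamin D, 25 higher and 54 lower for CCR10-positive against CCR10-negative and 198 higher and 158 lower for vitamin D against IL-12. It gave 31 higher and 17 lower for the shared vitamin D genes and 13 higher and 5 lower for the shared IL-12 genes. Median scaling, which shifts all genes of an array, gave 652 higher and 197 lower for retinoic acid against unstimulated, 1010 higher and 327 lower for IL-12 against unstimulated, 653 higher and 1601 lower for vitamin D against retinoic acid and 582 higher and 203 lower for CCR10-positive against CCR10-negative. It gave 486 higher and 1124 lower for vitamin D against IL-12 and 70 higher for the shared IL-12 genes. Quantile normalization gave 300 lower for CCR10-positive against CCR10-negative. The median over all probe sets gave 421 higher for IL-12 against unstimulated, 140 higher for CCR10-positive against CCR10-negative and 64 lower for the shared vitamin D genes. The CCR10-positive array alone, 1 condition in place of 2, gave 453 higher and 476 lower genes against IL-12 and 273 higher and 449 lower genes against vitamin D. The CCR10-negative array alone gave 900 higher and 615 lower genes against IL-12 and 394 higher and 369 lower genes against vitamin D. The mean log2 value of both sorted arrays gave 485 higher and 429 lower genes against IL-12 and 216 higher and 278 lower genes against vitamin D.

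These medians and ratios changed sign, and the cause was not tested. After quantile normalization the ribosomal protein median was 0.0377 for IL-12 against unstimulated, 0.0904 for CCR10-positive against vitamin D, 0.0221 between the sorted arrays and -0.0273 for vitamin D against IL-12. With the median over all probe sets the Th1 median was -0.0869 for IL-12 against unstimulated and 0.14 for vitamin D against IL-12, the activation list was -0.17 for CCR10-positive against vitamin D, CCR1 was 0.14 for vitamin D against retinoic acid, and HK2 was -0.038 between the sorted arrays. Without probe sets of less specific design the ribosomal protein median was 0.15 for CCR10-positive against vitamin D and -0.28 for vitamin D against IL-12, the other chemokine receptors -0.080 for CCR10-negative against vitamin D, red cell and platelet markers -0.14 for retinoic acid and housekeeping genes 0.0688 for IL-12 against unstimulated. The same change gave 0.096 for NEDD4L with vitamin D against unstimulated, 0.22 for COA1 with vitamin D against retinoic acid, 0.0084 for FAM13A with both sorted arrays against IL-12 and 0.13 for EPB41L4B with vitamin D against IL-12. A floor at the 75th percentile gave 0.065 for GZMM with vitamin D against retinoic acid and -0.0957 for ATP12A between the sorted arrays. With the IL-12 array as reference the retinoic acid receptor targets of the vitamin D array had a median of 0.18.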

Other observations

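The genes in this part were chosen after their values were seen. Heat shock and immediate early genes differed between members in the vitamin D arrays. DNAJB1, a heat shock cochaperone, was 2.61-fold higher in vitamin D than in unstimulated cells and 3.23-fold and 3.31-fold higher in the CCR10-positive and CCR10-negative arrays than with IL-12. HSPA6 was 4.47-fold, 20.01-fold and 26.5-fold higher in the same order. Its intensity was lower in the IL-12 array (146.6) than in the unstimulated array (793.2), which raises the ratios against IL-12. In that order the phosphatase DUSP1 was 3.2-fold, 2.1-fold and 2.44-fold higher, while FOSB had ratios of 1.06-fold lower against unstimulated and 2.72-fold and 2.39-fold lower against IL-12. The zinc exporter SLC30A1 was 2.77-fold, 3.48-fold and 2.78-fold higher, whereas the metallothionein list as a whole lay inside the central range in these ratios (0.06, 0.13 and 0.31). Over all genes above the floor on any array, 13.8% and 10.4% were in all 3 vitamin D arrays above or below the other 3 arrays, where 5% each would be expected if the 6 values were in random order. The same 3 arrays had the higher control ratios, so this excess cannot be assigned to vitamin D.

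Genes tied to the fate of T cells showed a mixed picture between treatments. CD28 was 2.44-fold higher in vitamin D than in unstimulated cells and ICOS 2.37-fold lower, and against IL-12 the CCR10-positive and CCR10-negative arrays had CD28 2.25-fold and 1.89-fold higher and ICOS 2.26-fold and 3.11-fold lower. CCR1 was highest in the CCR10-negative array (5589.7) and lowest in the unstimulated array (408). EOMES, a transcription factor of cytotoxic T cells, had intensities of 159.8, 161, 422, 818, 1273 and 3020.2 in the unstimulated, retinoic acid, IL-12, vitamin D, CCR10-positive and CCR10-negative arrays. VDR, the vitamin D receptor itself, was 2.12-fold higher with retinoic acid than without stimulus and had a ratio of 1.08-fold lower with vitamin D.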
